A study of Mus musculus with 5 samples.

How the data were processed

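Run-on RNA of mouse ES cells (line V6.5, 3 samples) and mouse embryonic fibroblasts (2 samples) had been sequenced by the authors. Per the labels' protocols, nuclei were run on with Br-UTP, the RNA was base-hydrolysed and enriched with an antibody against the brominated base, and the ES cells were grown on irradiated feeders with LIF while MEF were grown without LIF. The groups were taken from the sample titles. The series design text states that reads were aligned with Eland to mm9 and that reads in regions annotated by RepeatMasker as similar to rRNA were removed. Per the file headers, the libraries of each cell type were pooled and aligned to a genome without repeat masking. The Eland version, the treatment of reads with several matches and the treatment of duplicates are not given in the sources used here.

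The deposited files hold 1 line per aligned read with position, strand and sequence and a value of 1 in each line, so their unit is a raw read count, and the deposited files record no normalization of it. Signal tracks and sequence files were not used here. The reads of a cell type carry no sample name, so each file was treated as 1 pooled library. A test across replicates was therefore not made, in place of the edgeR test planned for separable samples. Positions were checked against the NCBIM37 assembly, which is mm9: of every 400th read, 92.9% in MESC and 95.5% in MEF matched the genome with at most 2 mismatches, with the listed position as the 5′ end on either strand. MESC reads were 35 or 36 bases long and MEF reads 35 bases, which was used only as a technical split.

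The MESC library held 8616592 reads and the MEF library 6583644, of which 74.4% and 71.3% lay at distinct positions and strands if each position is counted once. Gene bodies took 37.2% of MESC and 36.8% of MEF reads, and the 1% of genes with the most reads took 13.9% and 18.6% of these. Despite the removal step named in the design text, 2 loci similar to ribosomal DNA (chromosome 17, 39979000 to 39990000, and chromosome 13, 9828000 to 9836000) held 11.5% of MESC and 16.4% of MEF reads. They were left out of the chromosome shares and of the intergenic background but stayed in the scaling total, and an added alternative takes them out of that total.

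Genes came from the GENCODE annotation given for NCBIM37, with 1 model per gene, the longest transcript. Of 22885 models of at least 2000 bp, 2992 whose counted part overlapped another gene on the same strand were left out, which kept 19893. Reads were counted by 5′ end on the sense strand: gene bodies from 1000 bp after the TSS to the annotated end, promoter windows from 50 bp before to 300 bp after the TSS, and upstream antisense windows of 500 bp on the opposite strand. Density was RPKM, with only reads outside the mitochondrial genome in the total. Bodies entered the comparison with at least 50 reads in 1 library and promoters with at least 20. A gene counted as different at a ratio of at least 4, with 3 reads standing for any lower count. Ratios have exact conditional Clopper-Pearson 95% intervals, and shares have Clopper-Pearson intervals. No p-value was computed across genes between the cell types.

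A gene was active with at least 20 promoter-proximal reads or a body density whose Poisson interval lay above the intergenic background, 0.145 reads per kb and strand in MESC and 0.0843 in MEF, measured more than 10000 bp from genes. The pausing index was promoter-proximal over body density. A one-sided Fisher exact test per gene, with Benjamini-Hochberg adjustment at 0.05, compared both windows within a library. Indices were compared between libraries for genes with at least 20 reads in each window of both. Antisense shares used active promoters with no annotated TSS of another gene within 2000 bp.

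Before the data were examined, 25 gene lists with 470 genes were fixed: pluripotency; fibroblast and extracellular matrix; contractile and SRF targets; TGF-beta signalling; Nodal, LIF and FGF signalling; Hox clusters; lineage regulators; primitive endoderm; trophoblast; primed epiblast. Further lists covered the cell cycle, CDK inhibitors and p53 targets, DNA methylation and chromatin regulators, pausing and elongation factors, ribosomal proteins, immediate early genes, heat shock genes, glycolysis and imprinted genes. Lists of endothelial, blood and macrophage, skeletal muscle, neural, epithelial and cartilage markers stood for other cell types. A RefSeq name table placed 11 symbols by synonym, and 1 stayed unmatched. A list was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on density in 10 bins. A bootstrap interval of a median covers 95% of 2000 draws of its genes with replacement.

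Named genes followed a rule fixed at the same time. It took the 8 highest and 8 lowest body ratios among genes with at least 200 reads in the higher library, 9 anchor genes, and up to 4 members per list with the largest change. It also took the 5 highest and 5 lowest indices per library (highest with at least 100 promoter-proximal and 20 body reads, lowest with at least 200 body reads), the 5 largest changes of index each way, and the 5 promoters with the most antisense reads per library. Some genes that the rule takes are not reported here. Any other gene is named as an exception to a count and was chosen after its values were seen.

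The alternatives fixed at the same time were counting each position once, scaling by the median ratio or by TMM factors, other read minimums, a 2-fold rule, bodies from 500 or 3000 bp, the densest 250 bp window within 500 bp of the TSS, and the transcript start with the most reads. Others were protein-coding genes only, activity by body reads only, an index of at least 4 or 10, a 1000 bp antisense window and list means. Added after seeing the data were scaling without the ribosomal DNA loci, overlap judged by genes of at least 2000 bp only, each read length of MESC alone, and MESC thinned at random to 72.5% of its reads, the MEF depth outside the mitochondrial genome and the ribosomal DNA loci. Counting was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, TMM factors with edgeR 4.0.16 in R 4.3.3, and figures with matplotlib 3.10.9.

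The ratio step was tested on simulated counts for the 9488 gene bodies of the MESC and MEF comparison, with 200 genes changed. At a simulated 8-fold change 100% of the 200 genes were recovered, at a simulated 2-fold change 0% passed the 4-fold rule, and 0 of 9288 unchanged genes were called in either run. The simulated counts, also those for pausing below, held counting error alone. They check the calculation and do not give the rate of false calls in the data. The pausing test was tried on simulated counts for 12441 genes in MEF, with 200 genes given an index of 8. With a measured index of at least 2 also required, it found 70.5% of these and 0 of 12241 unchanged genes.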

Results

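Transcribing RNA polymerase was mapped in mouse embryonic stem cells (MESC, line V6.5, grown on irradiated feeder cells with LIF) and in mouse embryonic fibroblasts (MEF, from male embryos) by global run-on sequencing. In this assay engaged polymerases extend their transcripts in isolated nuclei with a brominated nucleotide, and the marked RNA is enriched and sequenced, so reads report polymerase position and strand rather than stable RNA. The series held 5 samples, 3 of MESC and 2 of MEF. The authors' files pooled the samples of each cell type, which left 1 read set per cell type and no spread between replicates for any value. The MESC file held 8616592 aligned reads and the MEF file 6583644. All differences are therefore differences between 2 pooled libraries with no replicate check, and whether the cell types differ was not tested. Intervals are exact 95% intervals that cover counting error only, because the samples of a cell type were pooled. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Density means reads per kb scaled to the reads outside the mitochondrial genome (RPKM), and a fold is the ratio of densities. Coordinates are mm9.

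The first comparison asked which genes carried more polymerase in each cell type. The core genes of the pluripotent state were read in MESC and hardly at all in MEF. The body of Tdgf1, which encodes a Nodal co-receptor (chromosome 9, 110842114 to 110848662), held 1024 reads in MESC and 0 in MEF, at least 262-fold higher in MESC against the floor of 3 reads. L1td1 and Lin28a, genes for RNA-binding proteins of early embryonic cells, held 835 and 699 reads against 0, at least 213-fold and 179-fold higher. The transcription factor gene Pou5f1 (chromosome 17, 35642982 to 35647721) held 163 reads against 3, a ratio of 41.7 (14.0 to 204), and Nanog held 162 against 2, a ratio of 62.1 (16.9 to 517). Zfp42, a widely used marker of undifferentiated cells, held 232 reads against 0, at least 59.3-fold higher in MESC. The other genes with the highest MESC ratios were Sall4 (769 reads against 1), the fatty acid transporter gene Slc27a2 (829 against 1), the germline gene Tdrd12 (696 against 1), Gm13235 (660 against 3) and Tsix (1217 against 6). Gm13235 belongs to a family of similar zinc-finger genes, so its reads are uncertain. Tsix, the antisense partner of Xist (chromosome X, 100626856 to 100680296), had a ratio of 155 (71.2 to 425). Sox2 held 92 reads against 4, but its model overlaps another gene of the same strand and it was left out of the counts.

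Genes of the contractile cytoskeleton and of the extracellular matrix carried the most MEF-biased polymerase. Acta2, smooth muscle actin (chromosome 19, 34315580 to 34329826), held 2182 reads in MEF and 15 in MESC, 190-fold higher in MEF (115 to 340). The collagen genes Col12a1 and Col1a1 (chromosome 11, 94797538 to 94814356) were 178-fold (121 to 276) and 73.7-fold (58.7 to 93.9) higher in MEF, and Col1a2 was 33.3-fold higher (28.4 to 39.3). The protease gene Pappa was 144-fold higher (100.3 to 216). Lrrc17, Postn and Actg2 held 382, 307 and 261 reads in MEF against 3, 1 and 1 in MESC. The fibroblast surface marker Thy1 was 13.0-fold higher in MEF (7.66 to 23.9). Of the 2 reference genes, Actb was 2.50-fold higher in MEF (2.22 to 2.81) and Gapdh 1.95-fold higher in MESC (1.69 to 2.25), and both directions held under every scaling tried.

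Among 9488 gene bodies with at least 50 reads in 1 library, 759 were at least 4-fold higher in MESC and 522 at least 4-fold higher in MEF. The split moved with the processing: 59.3% of the called genes were higher in MESC, against 48.4% under scaling by the median ratio, 48.1% with a read minimum 4 times as high, 53.6% with MESC thinned to the MEF depth and 43.8% with its 35-base reads alone. The median log2 ratio of all bodies tested was 0.30, and it was 0.06 under TMM factors. Group medians are to be read against 0.30, and for some of them the distance from it is given. When the reads of MESC were divided by length into 35-base and 36-base reads, a technical split of the pooled library, 13 of 7327 bodies differed 4-fold. The log2 ratios between these parts had a standard deviation of 0.37, against 0.20 from counting error alone.

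**Figure D1:**
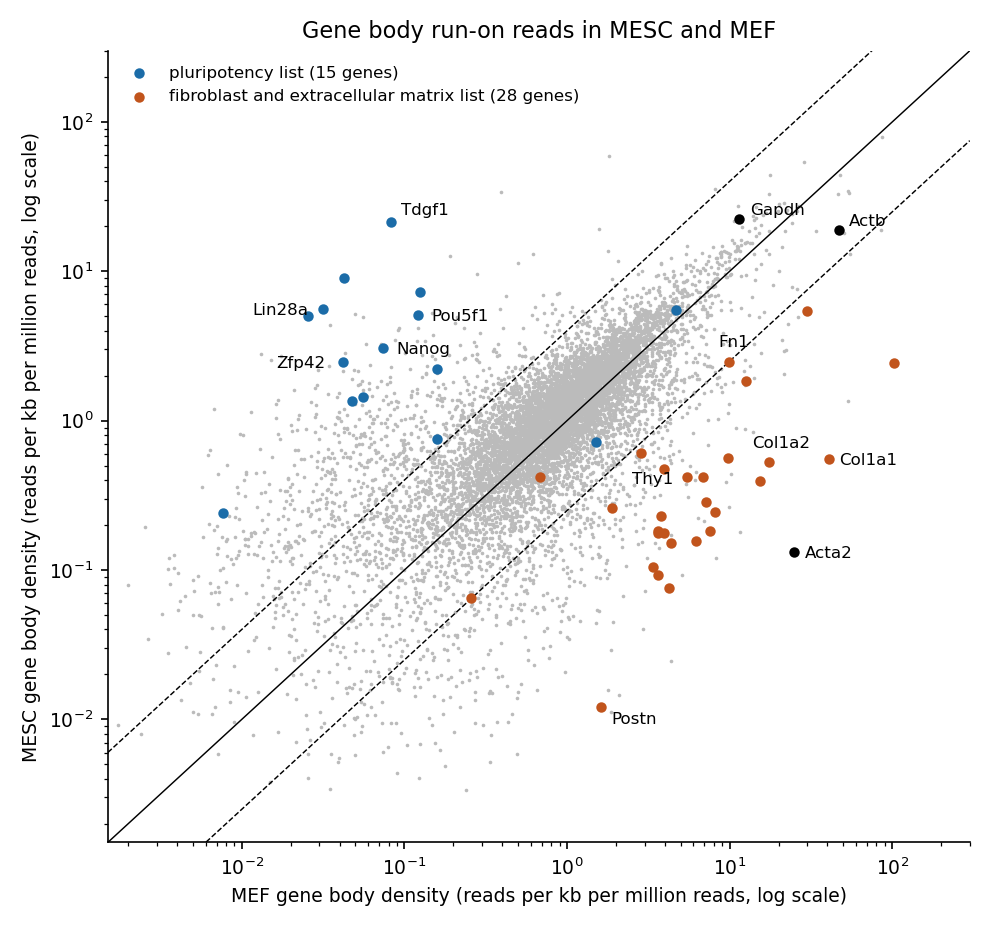
Gene body density in MEF (x axis) against MESC (y axis), both in RPKM on log scales, for 9488 genes, with counts below 3 set to 3. Blue points are the 15 measured pluripotency genes and orange points the 28 measured fibroblast and matrix genes; the solid line is equality and the dashed lines mark 4-fold, beyond which 13 blue and 25 orange points lie.

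Among gene groups fixed before the data were examined, those of pluripotency and epithelial identity leaned to MESC. Of 15 measured pluripotency genes 13 were at least 4-fold higher in MESC, and the exceptions, named after their values were seen, were Klf2 (log2 0.24) and Tbx3 (log2 -1.08). With counts below 3 set to 3, the group median was 41.4-fold, or log2 5.37, which is 5.07 above the median of all genes and above all 10000 random lists of matched density. In the group of Nodal, LIF and FGF signalling 7 of 15 genes passed 4-fold toward MESC. The Nodal antagonist genes Lefty1 and Lefty2 held 258 and 174 reads against 2 each, with ratios of 98.9 (27.1 to 821) and 66.7 (18.2 to 555), and Nodal itself held 178 against 2. The LIF receptor and pathway genes Lifr, Il6st, Stat3 and Socs3, named after their values were seen, had log2 ratios of -0.06, -1.48, -0.83 and -0.07. The group median of log2 1.42 lay above all random lists, but its bootstrap interval over members, -0.06 to 5.47, held the median of all genes. All 4 measured epithelial genes were at least 4-fold higher in MESC, among them Epcam, an adhesion gene (66.3-fold, 25.7 to 245), Cdh1, E-cadherin (28.5-fold, 21.6 to 38.3), and Krt8 (9.51-fold, 3.86 to 30.3). Cldn6 held 57 reads against 0; its model is 3082 bp long, and counted from 3000 bp after the TSS both libraries lay at or under the floor. The epithelial median was log2 4.35, above all random lists. All 5 measured primed-epiblast genes passed as well, with Otx2, a forebrain and epiblast regulator, at 132 reads against 1, Lef1 at 12.9-fold (10.4 to 16.4) and a group median of 7.33-fold (percentile 99.98).

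Fibroblast, contractile, TGF-beta and cartilage genes leaned to MEF. Of 28 measured fibroblast and matrix genes 25 were at least 4-fold higher in MEF and none in MESC, with a median of 21.3-fold, log2 -4.41, below all random lists. Thbs2 and Thbs1, thrombospondins of the matrix, were 55.8-fold (35.1 to 94.7) and 42.4-fold (37.8 to 47.8) higher in MEF. Of 17 contractile genes and targets of the serum response factor 12 were at least 4-fold higher in MEF, among them Myl9, a myosin light chain (15.2-fold, 9.40 to 26.2), Tgfb1i1 (12.3-fold, 9.22 to 16.7) and Ankrd1 (11.1-fold, 6.35 to 20.9), and the median was 5.48-fold. Of 16 TGF-beta pathway genes 6 passed toward MEF, among them the ligand gene Tgfb3 (25.8-fold, 16.8 to 41.6) and the activin subunit gene Inhba (24.5-fold, 18.3 to 33.5). That group's median was log2 -1.70, at percentile 0 of the random lists. Of 6 cartilage genes 5 passed toward MEF, with the collagens Col9a1 at 43.6-fold (18.3 to 136), Col11a1 at 29.9-fold (22.0 to 41.8) and Col2a1 at 8.42-fold (6.48 to 11.1), and the group median was 7.65-fold.

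Developmental regulators went both ways. Only 3 of 38 Hox genes could be measured, with Hoxc4 15.7-fold (6.35 to 50.0) and Hoxb3 4.66-fold (3.18 to 6.99) higher in MEF and Hoxb9 between the limits. Among 12 measured lineage regulators known as Polycomb targets, Gata4, Pax6 and Wt1 were 10.3-fold (5.42 to 21.9), 7.41-fold (4.86 to 11.8) and 7.04-fold (5.03 to 10.1) higher in MESC. Tbx15, a T-box gene of skeletal and dermal precursors, was 6.68-fold (5.84 to 7.67) higher in MEF, as were Tbx18 and Lmx1b (log2 -2.69 and -2.21), which were named after their values were seen. The group median was log2 -1.13, at percentile 0.10, with a bootstrap interval of -1.99 to 2.22. The primitive endoderm group was mixed: Lama1, a laminin chain, was 15.3-fold (10.6 to 22.9) higher in MESC, Pdgfra was 4.69-fold (4.05 to 5.44) higher in MEF, Gata4 of the lineage regulators belongs to this group too, and the median of 7 genes was log2 -0.21 (percentile 11.2). Of the trophoblast genes 1 was measured, Tcfap2c, with 57 reads in MESC against 2 (ratio 21.8, 5.78 to 185).

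Most growth and housekeeping genes lay within 4-fold. Cell cycle genes had 27 of 28 members within 4-fold. Their median of log2 0.71 lay 0.41 above that of all genes (percentile 99.8), with Ccnb1, Mcm2 and Aurka 3.33-fold (2.69 to 4.16), 3.17-fold (2.57 to 3.94) and 3.15-fold (2.53 to 3.94) higher in MESC. The exception was the D-type cyclin gene Ccnd2, 6.25-fold higher in MEF (5.22 to 7.53). Among 9 CDK inhibitor and p53 target genes, Trp53inp1 (8.06-fold, 6.54 to 10.0) and Perp (4.89-fold, 2.71 to 9.58) passed toward MESC, with a group median 0.65 above all genes (percentile 99.0). Of 22 chromatin regulators 3 passed toward MESC: the Polycomb gene Cbx7 (88.7-fold, 56.7 to 148), the de novo DNA methyltransferase gene Dnmt3b (24.7-fold, 17.8 to 35.3) and its cofactor gene Dnmt3l (4.80-fold, 3.26 to 7.32). The group median lay 0.32 above all genes (percentile 97.1), but its bootstrap interval, log2 0.21 to 1.08, held the median of all genes. Of 20 pausing and elongation genes 19 lay within 4-fold and the median lay 0.10 above all genes (percentile 73.5). Mycn was the exception, 9.20-fold higher in MESC (5.83 to 15.3), while Myc was 2.82-fold (2.24 to 3.57) and Aff1 3.12-fold (2.79 to 3.50) higher in MEF. All 27 ribosomal protein genes lay within 4-fold, 0.20 above all genes (percentile 92.6), with Rps20 2.50-fold higher in MESC (2.23 to 2.81).

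Stress, metabolic and imprinted genes mostly lay within 4-fold. Of 13 immediate early genes 2 passed toward MEF, Ier5 (7.35-fold, 5.53 to 9.92) and Egr2 (4.53-fold, 2.69 to 7.99), and the median lay -0.57 from that of all genes (percentile 2.40). All 10 heat shock genes lay within 4-fold, with Hsp90aa1 2.20-fold higher in MESC (1.79 to 2.71), Bag3 2.42-fold higher in MEF (1.98 to 2.95) and a median at percentile 70.7. All 13 glycolysis genes lay within 4-fold. Their median log2 was 0.25 under scaling by all reads and -0.05 under scaling by the median ratio, so no direction is given for the group (percentile 37.3). Of 8 imprinted genes 1 passed, Snrpn, a splicing-protein gene, 16.7-fold higher in MESC (11.9 to 24.2); the median log2 was 0.07 and turned to -0.23 under scaling by the median ratio and -0.17 under TMM (percentile 26.3).

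Markers of other cell types were checked in the same way. In the neural group Stmn2 and Elavl3 were 9.20-fold (7.06 to 12.2) and 4.76-fold (2.92 to 8.19) higher in MESC among 4 genes (percentile 95.1). The bootstrap interval of that group's median log2, -0.08 to 3.20, held the median of all genes. The 3 measured endothelial genes, Tek, Pecam1 and Vwf, lay within 4-fold, at log2 0.65, 1.61 and 1.72, with intervals of counting error past 4-fold for Pecam1 and Vwf (percentile 78.7). The single measured skeletal muscle gene, Ttn, had log2 0.07, which turned to -0.23 under scaling by the median ratio. The blood and macrophage group is described with the other observations.

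**Figure D2:**
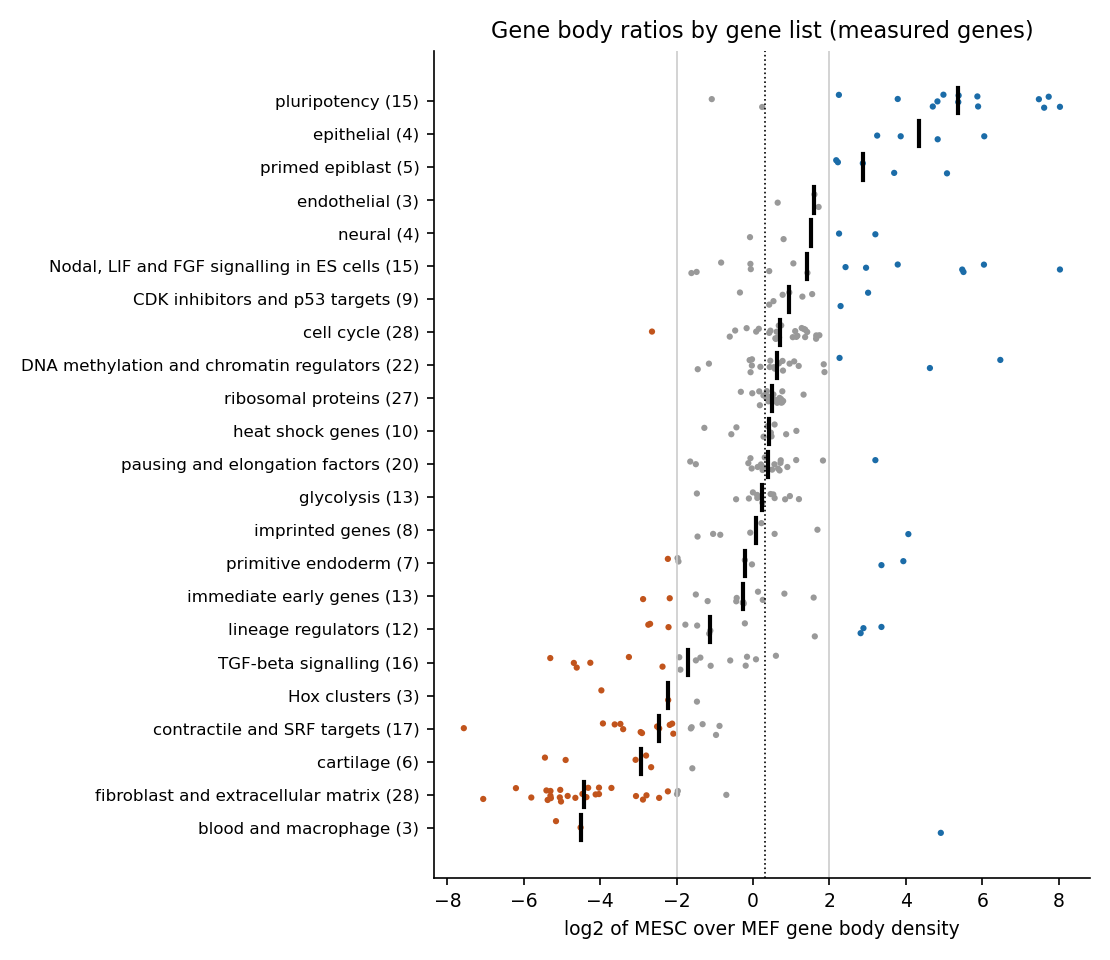
The log2 ratio of MESC over MEF gene body density (x axis) for each measured member of the gene groups with at least 3 measured genes (y axis, number measured in brackets). Points are genes, blue and orange where at least 4-fold higher in MESC and in MEF, black bars are group medians and the dotted line is the median of all genes, 0.30; medians run from -4.51 for 3 blood and macrophage genes to 5.37 for pluripotency.

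The next comparison asked whether the same differences held at the promoter, where polymerase enters. Reads were counted from 50 bp before to 300 bp after the TSS. Pou5f1 and Tdgf1 held 61 and 53 promoter-proximal reads in MESC and 0 in MEF, at least 15.6-fold and 13.5-fold higher. Acta2 and Postn held 181 and 89 such reads in MEF against 1 each in MESC, ratios of 236 (41.8 to 9376) and 116 (20.3 to 4636). Col1a1 was 38.5-fold (14.6 to 144) higher in MEF at its promoter and Col1a2 6.42-fold (3.50 to 12.7). Thbs1, 42.4-fold higher in MEF in its body, was 3.69-fold (2.80 to 4.92) higher at its promoter.

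Of 4350 promoter windows with at least 20 reads in 1 library, 264 were at least 4-fold higher in MESC and 131 in MEF. The share higher in MESC was 66.8%, against 53.7% under scaling by the median ratio, 56.0% with MESC thinned to the MEF depth, and 38.1% and 47.9% with its 35-base and 36-base reads alone. Across 3757 genes with both windows measured, body and promoter ratios correlated with r = 0.71 and rho = 0.54, a value across genes, which are not independent replicates. Among body-called genes with a measured promoter, 99 of 163 higher in MESC and 79 of 120 higher in MEF were also 4-fold different at the promoter in the same direction. Of the 395 promoter-called genes, 90 had body ratios under 2-fold. This count set no minimum of body reads, with counts below 3 set to 3, so it may include bodies with too few reads to compare. When reads at 1 position were counted once, 119 and 73 promoter windows were above 4-fold.

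Pausing was measured in each library as the ratio of promoter-proximal to gene body density, the pausing index. Among genes with at least 100 promoter-proximal and 20 body reads in the library, the index was highest at Ndufs7, a gene for a subunit of respiratory complex I, with 556 in MESC and 788 in MEF. A single position of that promoter (chromosome 10, 79711898) held 1503 of its 1844 MESC reads and 857 of its 1533 MEF reads. Taf4b, a gene for a subunit of the general factor TFIID, had an index of 309 in MESC and 455 in MEF over 488 and 249 promoter-proximal reads. The other 3 of the 5 highest were Pate2, Slc18a1 and Mpp7 in MESC, at 536, 234 and 215, and 4933427G17Rik, 9030617O03Rik and the transferrin receptor gene Tfrc in MEF, at 733, 244 and 193. In MESC 4933427G17Rik had an index of 908, but over 16 body reads. Pate2, Slc18a1 and 4933427G17Rik had an annotated TSS of another gene within 2000 bp, so their promoter-proximal reads may belong to a neighbour. At the other end, genes such as Macf1 (3875 body reads), Aff3 (2502), Chd7 (2131), Nrf1 (1899) and Zfand3 (1805) had no promoter-proximal reads in MESC at the annotated start used. The same held for Rbms3, the fibrillin gene Fbn1, Cacna1c and Etv6 in MEF, with 5416, 4893, 3839 and 2793 body reads. The non-coding gene 9330185C12Rik also had none in MEF, where most of its 11487 body reads lay at adjacent positions of a single site. With each position counted once, its body ratio turned from log2 -1.63 to 1.61.

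Of 13258 active genes in MESC 64.8% (64.0 to 65.6) had an index of at least 2, and of 12441 in MEF 63.0% (62.1 to 63.8). The median index was 3.85 in MESC and 3.66 in MEF. A one-sided Fisher exact test per gene was adjusted by the Benjamini-Hochberg method and speaks only of the reads of its library. An index of at least 2 together with a pass in this test was found in 55.6% of active genes in MESC and 51.8% in MEF. A pass depends on read depth, which was greater in MESC, so these shares do not compare the cell types. An index of at least 10 was reached by 25.1% in MESC and 25.6% in MEF, the reverse order. The shares at index 2 depended on where the promoter was placed: with the TSS that held the most reads, they were 75.5% in MESC and 73.7% in MEF. Of 42 lineage regulators with a usable model, 31 were active in MESC and 8 of them passed that Fisher test, against 28 and 9 in MEF. Of 21 Hox models 11 were active in MESC and 17 in MEF, with 3 and 6 passing.

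The pausing index was then compared between the libraries, gene by gene. Etv5, an ETS factor gene downstream of FGF signalling (chromosome 16, 22381382 to 22439792), had similar promoter-proximal counts, 116 in MESC and 108 in MEF, but 2047 body reads in MESC against 202 in MEF. Its index was 9.27 in MESC and 87.5 in MEF. The coactivator gene Ncoa3 went the same way with 8.17 and 51.0, as did Gm16517 (2.18 and 11.1), the ubiquitin-conjugating enzyme gene Ube2s (4.90 and 24.6) and the zinc-finger gene Zbtb45 (2.14 and 10.6). Thbs1 (chromosome 2, 117937612 to 117952869) showed the reverse, an index of 9.57 in MESC, with 70 promoter-proximal and 297 body reads, and 0.83 in MEF, with 198 and 9658. Col11a2 (log2 change 2.72), Frmd6 (31.4 and 6.32), the kinase gene Tec (93.0 and 21.1) and the ubiquitin ligase gene Cblb (60.6 and 13.9) also had the higher index in MESC. At all 5 of these genes the body ratio favoured MEF. The ES cells were grown on feeders, so the MESC reads of a fibroblast-list gene such as Thbs1 may come in part from feeder cells.

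Of 2237 genes with at least 20 reads in both windows of both libraries, 7 had an index at least 4-fold higher in MESC and 15 in MEF. The median index of these genes was 12.5 in MESC and 14.9 in MEF, and 83.5% of the log2 changes lay within 2-fold of their median of -0.23. With each position counted once, 2 genes were higher in MESC and 3 in MEF. Between the 35-base and 36-base parts of MESC, 2 of 1445 genes differed 4-fold in index. The log2 changes between these parts had a standard deviation of 0.535, against 0.407 from counting error alone. Over the 1273 of these genes with MEF counts, the standard deviation between MESC and MEF was 0.690. Each part holds fewer reads than the whole MESC library, which raises its counting error, so these spreads cannot be compared directly.

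**Figure D3:**
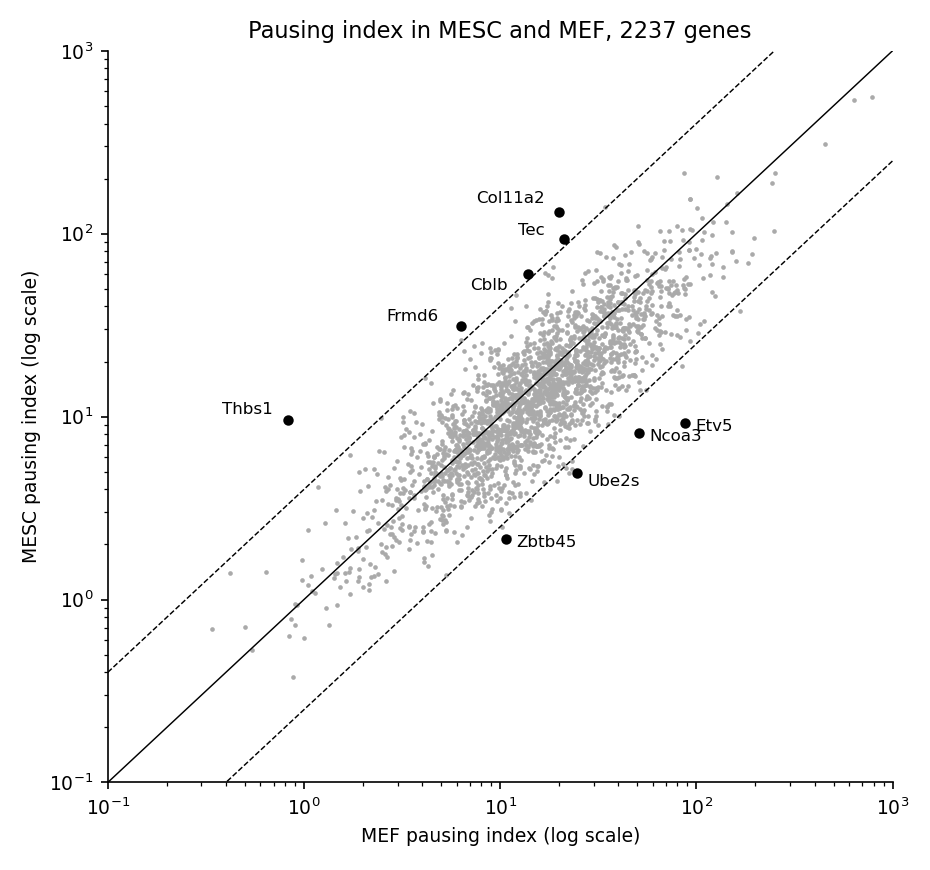
Pausing index (promoter-proximal over gene body density) in MEF (x axis) against MESC (y axis), both on log scales, for 2237 genes with at least 20 reads in each window of each library. The solid line is equality and the dashed lines mark 4-fold; 7 genes lie above and 15 below the dashed lines, with named genes in black, among them Thbs1 at 9.57 in MESC and 0.83 in MEF and Etv5 at 9.27 and 87.5.

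**Figure D4:**
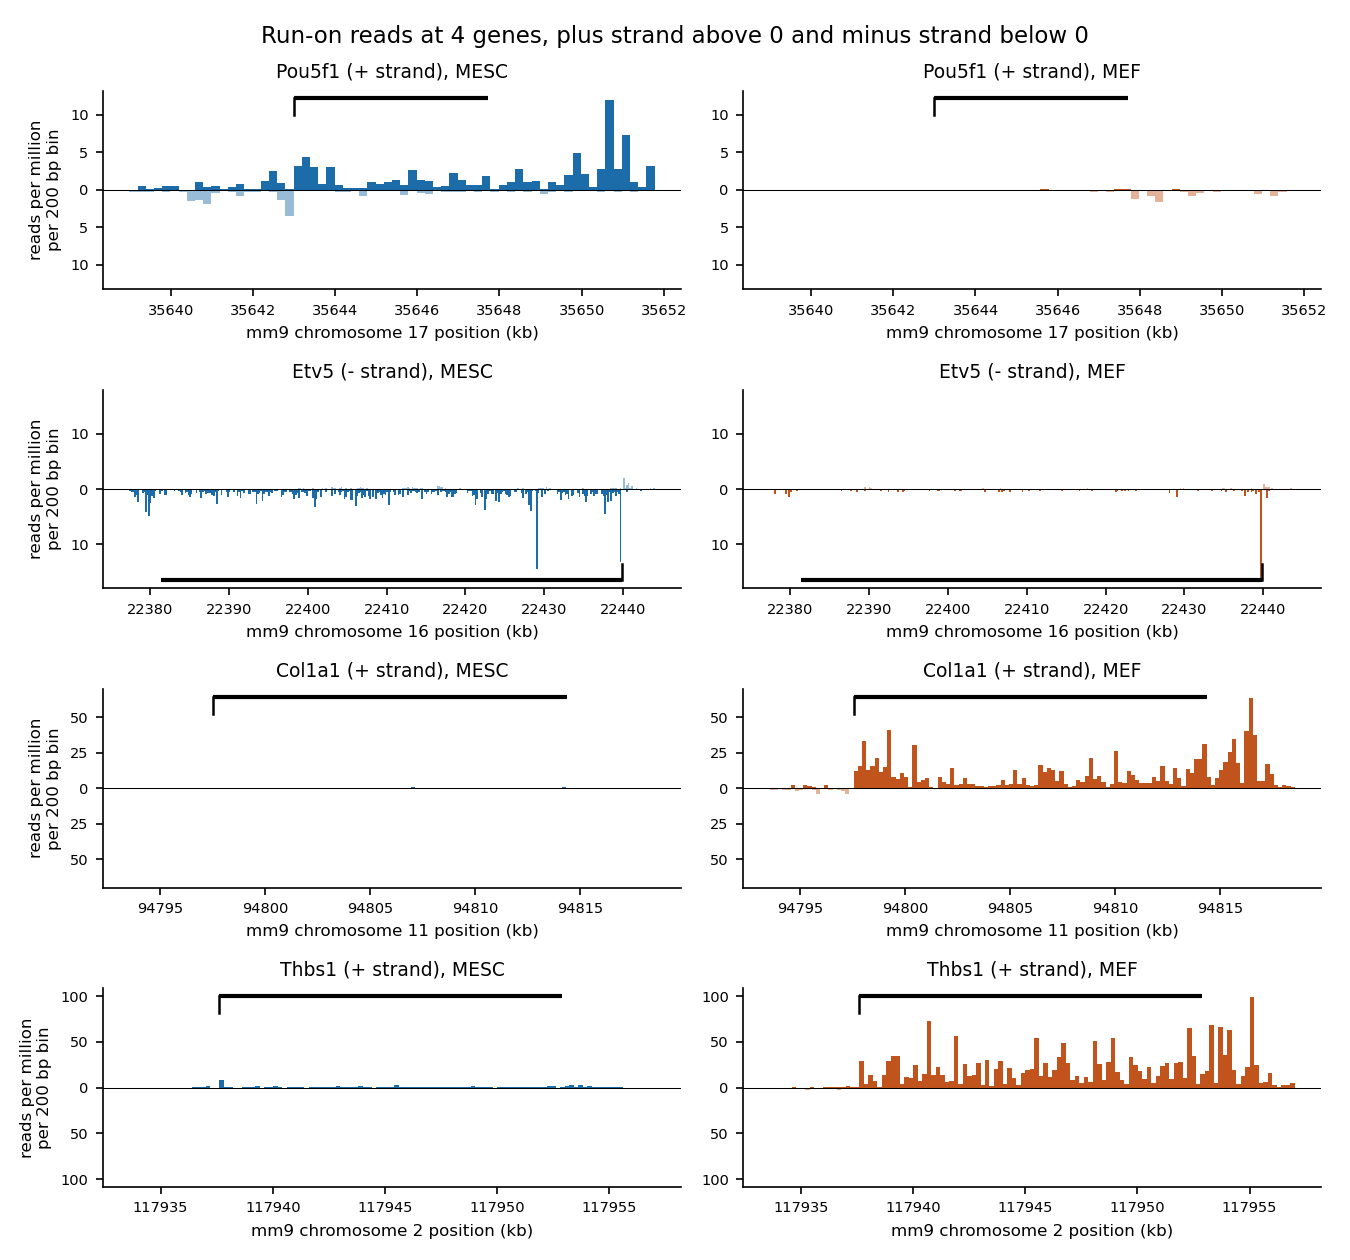
RPM in 200 bp bins (y axis) along Pou5f1, Etv5, Col1a1 and Thbs1 with 4000 bp on either side (x axis, mm9 position in kb), MESC in blue on the left and MEF in orange on the right, plus strand above and minus strand below the zero line. Black bars are the gene models with a tick at the TSS, and both panels of a gene share 1 scale; Etv5 shows a promoter peak in both libraries (116 and 108 reads) and a filled body in MESC.

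The last comparison asked how often promoters were transcribed divergently, that is, in the antisense direction upstream of the TSS. The promoters with the most upstream antisense reads differed in part between the libraries. At Prmt5, an arginine methyltransferase gene, 2473 antisense reads were counted in MESC and 1620 in MEF, of which 1859 and 1041 lay at 1 position (chromosome 14, 55136527). B3gnt1, a glycosyltransferase gene, held 2383 in MESC and 2851 in MEF, and Rab11a, a vesicle-trafficking GTPase gene, 2321 in MESC and 117 in MEF. Sacm1l and Gm17712 held 956 and 803 in MESC and 208 and 185 in MEF, and Ndufs7 held 791 in MESC and 1765 in MEF. The double-stranded RNA-binding protein gene Ilf2 and the mitochondrial polymerase gene Polg, among the 5 highest in MEF, held 620 and 553 in MESC and 607 and 566 in MEF. All of these are raw antisense counts, not scaled for the larger MESC library. Sense reads in the promoter window were few at Rab11a (4 in MESC, 5 in MEF), B3gnt1 (13, 7), Sacm1l (3, 9) and Gm17712 (8, 4). They numbered 46 and 45 at Prmt5 and 1844 and 1533 at Ndufs7. Whether the antisense reads at the promoters with few sense reads reflect divergent transcription was not tested.

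Among active promoters with no other annotated TSS within 2000 bp, 66.3% (65.4 to 67.3) of 9619 in MESC had antisense reads above the intergenic background. In MEF the share was 56.0% (55.0 to 57.0) of 9006. Over all these promoters, 82.7 antisense reads were counted per 100 promoter-proximal sense reads in MESC and 68.8 in MEF. The share in MESC depended on depth and was 62.4% after thinning to the MEF depth, an alternative chosen after seeing the data. Sense reads peaked 25 to 49 bp after the TSS and antisense reads 151 to 175 bp before it in both libraries.

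**Figure D5:**
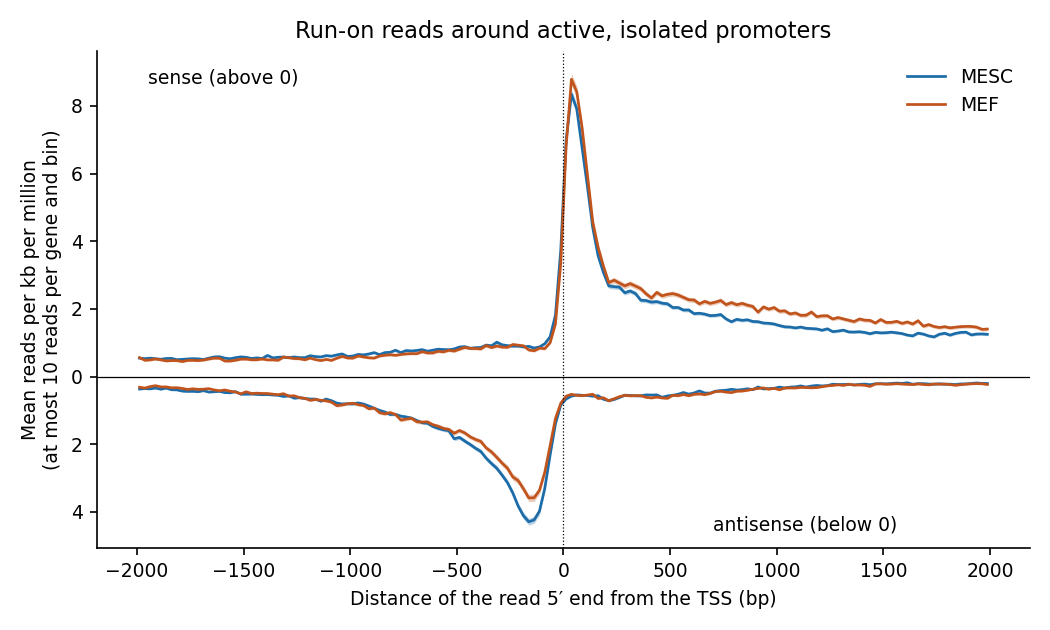
Mean density of read 5′ ends (RPKM, at most 10 reads per gene and bin) in 25 bp bins (y axis) against distance from the TSS (x axis, bp), for 9619 promoters in MESC (blue) and 9006 in MEF (orange). Sense reads are drawn above 0 and antisense reads below, shading is the standard error over promoters, and the antisense peak reaches 4.29 in MESC and 3.59 in MEF.

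The shares of reads per chromosome needed no gene annotation. Outside the mitochondrial genome and 2 loci similar to ribosomal DNA, chromosome X took 2.35% (2.34 to 2.36) of the reads in MESC and 1.99% (1.98 to 2.01) in MEF. Chromosome Y took 0.0214% (0.0204 to 0.0225) and 0.0255% (0.0242 to 0.0269). The largest ratio among autosomes was 1.14 for chromosome 8, with 5.44% in MESC and 4.78% in MEF, and the smallest 0.865 for chromosome 16. Plus-strand reads made up 50.7% of MESC and 50.4% of MEF reads outside these regions, and 51.0% and 50.7% when each position was counted once. Over all reads the shares were 54.3% and 54.4%.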

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

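All tests of explanations in this part were chosen only after the results were seen. Reads outside the gene comparisons held several signals above the limit that a count of 0 allows. Loci similar to ribosomal DNA held 11.5% of MESC and 16.4% of MEF reads, and the mitochondrial genome 0.525% and 0.190%. The 5.8S rRNA gene n-R5-8s1 (chromosome 18, 73693057 to 73693204, minus strand) held 30149 reads in MESC and 105 in MEF. Outside genes and the ribosomal DNA loci, the highest single position in MESC was on the mitochondrial genome with 18252 reads, against 360 in MEF. The highest in MEF was on chromosome 11 at 108872994 with 7047 reads, against 5370 in MESC. More than 10000 bp from genes, 288 bins of 10000 bp were at least 4-fold higher in MESC and 113 in MEF, and they are described with the other observations.

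Genes of the fibroblast list, of which 2 also stand in other lists, had reads in the MESC library, made from cells grown on irradiated feeders. Summed over the 28 measured genes, the scaled MESC body reads were 6.18% of those in MEF, and the ratio per gene ranged from 0.250% for Postn to 61.6% for Mmp2, with 2.36%, 3.03% and 4.87% for Thbs1, Col5a1 and Fbn1, which held the most MEF reads. MEF-like feeder cells at 1 constant share stay open: no share lay inside the counting interval of more than 10 of the 28 genes, but counting error leaves out the spread between preparations, and with each interval widened 4-fold both ways 1 share lay inside 26. Whether the reads keep the MEF ratio of promoter to body reads stays open: the promoter ratio exceeded the body ratio in 13 of 16 list genes, with a median log2 difference 1.18 above that of 1884 genes with bodies under 2-fold, but the body ratio predicts fewer than 3 MESC promoter reads for 9 of the 16, and the other 7, of which 5 went the same way and whose median lay 0.97 above that of the same 1884 genes, are too few to decide. These feeders, feeders that differ from the MEF sequenced here, transcription by the ES cells themselves and a mixture cannot be told apart, because no library without feeders was analysed here, and any of them may contribute to the 6.18%.

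The median gene body lay above 0 toward MESC, by log2 0.30. Reads at the ribosomal DNA loci are argued against as the whole cause, since the median stayed at 0.22 without them in the totals. The 1% of genes with the most reads in each library are argued against as the whole cause as well, since the median was 0.19 when they and those loci left the totals. An uneven spread of reads over more genes than that 1% was not tested and stays open. A dependence on gene length is a candidate explanation for part of it: from the shortest to the longest of 5 length classes of gene bodies the medians were 0.38, 0.40, 0.33, 0.26 and 0.04, a span of 0.36 that rests mainly on the longest class. Densities are scaled to the reads of each library, so a uniform difference in the amount of transcription would cancel and could not move this median. Whether the amount differs between the cell types was not tested, because these reads hold no external standard.

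Promoters with upstream antisense reads made up a larger share in MESC, 66.3% against 56.0%. Greater depth is argued against as the whole cause, because the share was 62.4% after MESC was thinned, above the MEF interval of 55.0 to 57.0, although the smaller 35-base and 36-base parts of MESC gave 56.1% and 59.5%. Different sets of active promoters are argued against too: over 8173 promoters active in both libraries the share was 67.8% in thinned MESC and 59.9% (58.8 to 61.0) in MEF. A difference between library preparations and one between the cell types cannot be told apart, since no preparation holds both. The lower of the 35-base and 36-base parts of MESC lay 9.87 antisense reads per 100 promoter-proximal reads above MEF, while the parts differed from each other by 6.82, so either may account for the difference.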

How the results depend on the processing

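The alternatives named below as added were chosen only after seeing the data, and the others were planned. No paired analysis was possible because the files pool the samples of each cell type and carry no replicate number. For the same reason leaving out each replicate, separate sequencing runs or lanes, the replicate block and DESeq2 were not run. The comparison of genome bins was used only for counts outside genes, with none of its alternatives run, because an annotation of the build was given, and the 2-fold rule gives no other value for list medians. Over 21 settings, the bodies of the 137 genes that the rule takes changed sign in 14 values, from 9330185C12Rik, Ttn, Gap43, Cldn6, Macf1, B3gnt1 and Gm17712. With each position counted once, 9330185C12Rik turned from log2 -1.63 to 1.61. Of the 76 at least 4-fold different, only Cldn6 turned, to log2 -0.38 for bodies from 3000 bp, which leave almost nothing of its model. Of 1281 called bodies, 1186 were also called with each position counted once, 1141 under scaling by the median ratio, 1165 under TMM, and 938 and 979 with the 35-base and 36-base reads of MESC alone (added). The share of called bodies higher in MESC ranged from 43.8% with the 35-base reads (added) to 62.2% under the 2-fold rule, against 59.3% in the result reported.

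Counts moved by over 1.5 times, and shares beyond their intervals, as follows. Each position counted once gave 119 and 73 promoters (MESC and MEF), 2 and 3 index changes, 63.1% of MESC genes at an index of 2, and plus-strand shares of 51.0% and 50.7%. Without a read minimum 1308 and 837 bodies and 250 MEF promoters passed; with a minimum 4 times as high 284 and 307 bodies and 34 and 17 promoters did. A read minimum sets how many genes are tested. With the higher one, body calls toward MESC fell from 759 to 284 and those toward MEF from 522 to 307. The cause of this unequal fall was not tested. The 2-fold rule gave 1968 and 1197 bodies and 918 and 409 promoters. Bodies from 500 bp gave 62.0% of MEF genes at an index of 2 and 12 index changes toward MESC, and bodies from 3000 bp 64.6% for MEF; the cause was not tested. The densest 250 bp window gave 80.4% and 79.0%, with 12 and 24 index changes, and the TSS with the most reads 75.5% and 73.7%. Both choose the window by its reads. An index of at least 4 was reached by 49.0% and 48.0%, and of at least 10 by 25.1% and 25.6%. A 1000 bp antisense window gave 73.1% and 64.0%.

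With fewer MESC reads, all added alternatives, the values were lower. The 35-base reads gave 459 bodies and 102 promoters higher in MESC, 63.3% at an index of 2, 4 index changes and 56.1% antisense. The 36-base reads gave 148 promoters, 62.2% and 59.5%, and thinned MESC reads 172 promoters and 62.4% antisense. With all reads, 4350 promoter windows and 9488 gene bodies reached their read minimum.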

Other observations

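The blood and macrophage list was fixed beforehand; the other values and tests in this part were chosen only after the data were seen, and none has an explanation attached. Genes of macrophages were read in the MEF library. Csf1r, the receptor for the macrophage growth factor, held 82 body reads in MEF and 1 in MESC, a ratio of 107 (18.7 to 4276). Sfpi1, the myeloid transcription factor gene also called Spi1, held 70 against 4, 22.8-fold higher in MEF (8.53 to 86.1). The lysozyme gene Lyz2 held 46 against 1 and the leukocyte gene Ptprc 35 against 4, both below the minimum of 50 reads. Cd34, a surface protein of blood progenitors and other cells, went the other way with 118 reads in MESC and 3 in MEF, a ratio of 30.2 (10.1 to 148). The group's 3 measured genes had a median log2 of -4.51, at percentile 0.060 of the random lists. Its bootstrap interval over members, -5.16 to 4.91, held the median of all genes.

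Transcription far from annotated genes also separated the libraries. Of 747 bins of 10000 bp and 1 strand with at least 50 distinct positions, 288 were at least 4-fold higher in MESC and 113 in MEF, counted by distinct positions. The highest in MESC was on chromosome 13, 19610001 to 19620000, minus strand, with 556 positions against 2; its nearest coding gene, Epdr1, lay 64 kb away. Another on chromosome 4, 145850001 to 145860000, plus strand, 21 kb from the zinc-finger gene Rex2, held 525 positions against 3. Of the 3 bins with the highest MEF ratios, 2 were the plus and minus strands of chromosome 11, 94740001 to 94750000, 48 kb from Col1a1, with 114 and 101 positions in MEF against 2 and 0 in MESC. The other lay on chromosome 2, 117570001 to 117580000, plus strand, 358 kb from Thbs1, with 104 positions against 1. A bin on chromosome 3, 145350001 to 145360000, plus strand, 37 kb from the matricellular protein gene Cyr61, held 96 positions in MEF against 3.

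Genes of the Y chromosome gave unequal ratios between the libraries. The histone demethylase gene Kdm5d held 6 body reads in MESC and 99 in MEF, while Uty held 765 and 416, Ddx3y 81 and 153, and Eif2s3y 117 and 107. These are raw counts, and the MESC library held more reads, so equal counts mean a lower density in MESC. By chromosome, the median log2 of gene bodies was highest on chromosome 8, at 0.51 over 512 genes (bootstrap interval 0.41 to 0.59), and lowest among the autosomes on chromosome 1, at 0.17 over 556 genes (0.07 to 0.29).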
